A study of Homo sapiens with 6 samples.

How the data were processed

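Gene expression was measured in 6 libraries of total RNA from human aortic smooth muscle cells, 3 transfected with control siRNA (siCon) and 3 with H19 siRNA (siH19), all taken 48 h after transfection. Per the labels' protocols, ribosomal RNA was depleted and stranded paired-end libraries were sequenced on an Illumina instrument. Per the submitters' processing notes, the authors used TopHat2 2.1.1, featureCounts 1.5.0, DESeq2 1.14.1 and R 3.3.3 with the genome build hg38. The strand setting of the counting, whether reads or fragments were counted, and the source of the annotation are not given in the sources used here. Genes that overlap another gene, on either strand, or that have near-identical copies can therefore share or lose reads. Genes with at least 50% of their exon bases shared with 1 other gene are called uncertain. The siRNA sequences are not given in the sources used here.

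The deposited count table holds whole-number counts per gene for each library and the summed exon length of each gene. It has 26485 gene rows and no row without a gene. In 28 rows the symbol had been turned into a date, and these genes are not named. The authors' deposited comparison table holds, per the file headers, a mean normalised count (signal) over libraries, a log2 fold change and its standard error, a Wald score, and p-values with adjusted p-values. It holds genes with adjusted p-values up to 0.0999 only. Its fold changes have the sign of siH19 over siCon, which was found from the counts. Groups and replicate numbers were taken from the sample titles.

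Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by TMM, and siH19 was tested against siCon with the quasi-likelihood F test, without covariates and with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of F. The fit has 4 residual degrees of freedom. The biological coefficient of variation was 11.4%. CPM values given as mean ± SD over 3 libraries are TMM-scaled, whereas those for H19 use library totals without TMM scaling. Except where another p is printed, every named gene described as risen or fallen passed the adjusted p of 0.05 in this test. For H19, which the filter removed, the planned edgeR test could not be made, and a two-sided exact permutation test of log2(CPM + 1) was used. The pseudocount of 1 CPM was chosen after the zero counts were seen. A count of 0 was taken to allow up to 3 counts. Intervals and limits of this kind cover counting error only, since PCR copies are not independent molecules.

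The 26 gene lists, the rule for named genes, and the tests and alternatives were fixed before the data were examined, except for the pseudocount of the H19 test, the 3 alternatives named as added, and the tests of the closing observations. The rule takes H19 and IGF2, the 8 largest rises and the 8 largest falls, the members of each list with the 2 smallest adjusted p (4 where the list passed), and ACTA2, TAGLN, MYH11, CNN1 and MYOCD. The result for 1 gene that this rule takes is not reported here. The largest changes were taken among genes past the threshold, with a mean of at least 5 CPM and groups that did not overlap, leaving out genes without an official symbol, small RNA genes, mitochondrial genes, XIST and Y-linked genes. Lists with at least 5 tested members (23 of 26) were tested with camera of limma 3.58.1 on log2 CPM (prior count of 2), with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists. With the preset correlation 6 lists passed. With an estimated correlation 0 lists passed at an adjusted p of 0.05, and 1 had an unadjusted p under 0.05. With fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, 17 lists passed, that is all but the contractile, basement membrane, p53, cholesterol, methylation and stress lists. The mitochondrially encoded list had 0 members in the table. Adjusted over the list alone, the counts of higher and lower members were the same as over all genes, except for 39 higher in the replication list, 4 lower in the contractile list, 9 higher among let-7 targets, 10 higher among p53 targets and 7 higher in the immediate-early and stress list.

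Gene coordinates are those of the deposited count table (hg38). GENCODE version 29 gave GC content, gene class and 3' UTR sequence, and 92.9% of symbols were matched to it. GC content was known for 97.8% of the tested genes. The alternatives were 3 other scalings, DESeq2 1.42.0, limma-voom, 2 other filters, a block for the replicate number, removal of the gene length trend, stricter thresholds and leaving out each library. Removal of the GC trend, thinning to the smallest total, and leaving out MTRNR2L and small RNA genes were added after the data were seen. Counts were simulated with the real means and library sizes (13203 genes), with a small part of the genes changed, as often up as down. There edgeR recovered 43.3% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 100% of those changed 4-fold. Of its calls, 7.93% were unchanged genes. In the real data 59.9% of genes passed, so these shares do not describe the real calls. Sites in 3' UTRs were tested with Python 3.11.15 and numpy 2.4.6. For each 7-mer, log2 fold changes were compared between genes with and without it, after regression on UTR length and GC content, exon length, gene GC content and mean expression. Genes were protein-coding, with a mean of at least 1 CPM and a UTR of at least 50 bases. Permutation of the values over genes was done 100 times. In simulated data, 3 of 3 planted sites with a shift of -0.3 were recovered. The values had been permuted over genes, so C-rich 7-mers did not compete there as in the real data. The shift was larger than the -0.13 and -0.18 of the 2 lowest 7-mers in the real data. The smallest lead in z over the next unrelated 7-mer was 1.65, under the 2 set in advance as evidence for a seed. The simulation thus does not show that a weaker site would be found.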

Results

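RNA was sequenced from primary human aortic smooth muscle cells, the contractile cells of the artery wall, bought from a supplier and kept in medium with growth factors and serum. The cells were transfected with a control siRNA (siCon) or with an siRNA against H19 (siH19), an imprinted long non-coding RNA next to IGF2 that is best known from fetal tissue. RNA was taken 48 h later, from 3 samples per group. The comparison asks how expression profiles differ between siCon and siH19 cells. Total counts were 13011678, 13545535 and 14524987 in siCon libraries 1, 2 and 3, and 22110752, 24173598 and 24623650 in siH19 libraries 1, 2 and 3. Each siH19 library was deeper than each siCon library, which is as far apart as 3 against 3 samples can lie (two-sided exact permutation p = 0.1, the smallest this design allows). No batch is given in the sources used here, so a batch that follows the groups cannot be told apart from the siRNA.

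The siCon and siH19 libraries also differed in composition. MTRNR2L genes, nuclear copies of the mitochondrial ribosomal RNA, took 8.62% ± 1.30 of the counts in siCon and 5.04% ± 0.23 in siH19 (SD, n = 3 each). Small non-coding RNA genes took 1.74% ± 0.49 and 2.82% ± 0.25. Replication-dependent histone genes took 0.0736% ± 0.0148 and 0.198% ± 0.009. For each of these shares the groups did not overlap (two-sided exact permutation p = 0.1). Among the siCon libraries, number 1 stood apart. The chi-square per degree of freedom over genes was 27.1 and 36.2 for its pairs with the other siCon libraries and 7.16 for the pair of those others. The pairs of siH19 libraries gave 5.77, 6.55 and 6.96. All of these exceed sampling noise, so no library was a copy of another.

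H19, the target of the siRNA, had almost no counts in either group. The gene (chromosome 11, 1995176 to 2001466, minus strand, hg38) had 0, 2 and 0 counts in siCon libraries 1, 2 and 3 and 0, 0 and 0 counts in the siH19 libraries. A count of 0 allows up to 0.207 to 0.231 CPM in a siCon library and 0.122 to 0.136 CPM in a siH19 library. These limits use library totals without TMM scaling and cover counting error only. Both groups lay at or under these limits, so no fold is given, and H19 did not pass the expression filter of the edgeR fit. The exact permutation test of log2(CPM + 1) gave a two-sided p of 1. With counts in only 1 library, every split into 3 and 3 gives a difference of the same size. This p was therefore fixed by the zero counts and tells nothing about the H19 level. The counts therefore do not check which libraries received the H19 siRNA, and a lower H19 level was not detectable in them. MIR675, the microRNA gene inside H19, and the overlapping gene HOTS had 0 counts in all 6 libraries. Their summed exon lengths (146 and 7775 bases) exceed their spans on chromosome 11 (1996759 to 1996831 and 1992408 to 1996294). They are therefore listed at more than 1 place, and H19, which overlaps them, may be too. Reads that match more than 1 place may not have been counted, so the low counts do not show that H19 RNA was absent. IGF2, the neighbouring growth factor gene, had 1 count in all 6 libraries together. H19 shares 16.6% of its exon bases with HOTS, and IGF2 shares 76.1% with INS-IGF2. The counting can therefore leave reads of these genes out or divide them. Overlap was taken on the main chromosomes only, so the H19 share may be too low if its exon length includes copies elsewhere.

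A large part of the transcriptome differed between siH19 and siCon. Of 13372 genes tested, 4031 were higher and 3976 were lower in siH19 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 59.9% of the genes. At least 2-fold changes were seen for 1468 higher and 1339 lower genes, and at least 4-fold changes for 214 and 207. The 3 siH19 values lay all above or all below the 3 siCon values for 67.3% of genes, against 10% by chance. No label says that the samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The split depends on the scaling. With library totals only, the median of all genes moved by 0.29 (log2) and the calls became 5966 higher and 2521 lower, or 70.3% higher. Tested against a fold of 1.5, 1618 genes were higher and 1708 lower.

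**Figure D1:**
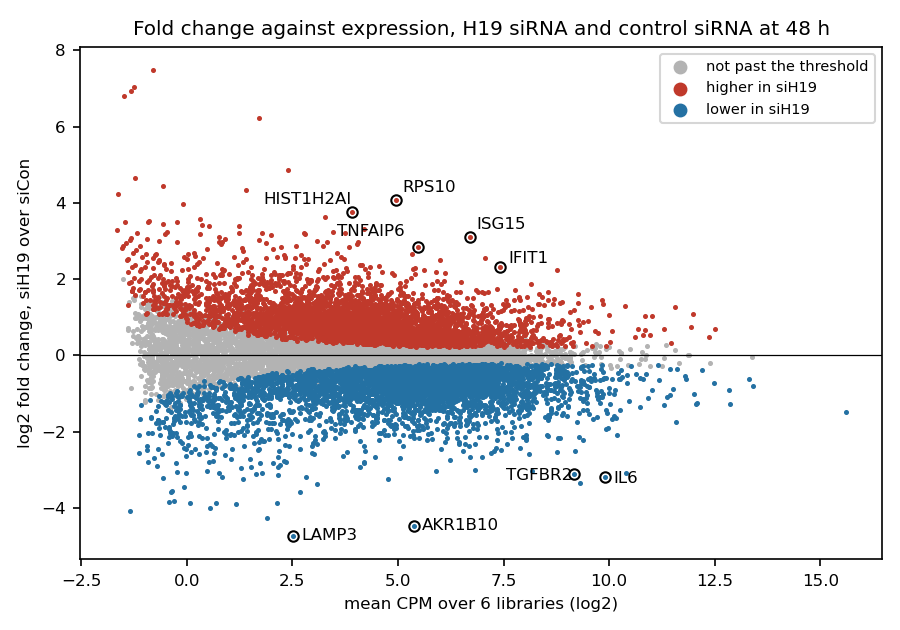
Log2 fold change of siH19 over siCon (vertical axis) against the mean CPM over 6 libraries (horizontal axis, log2) for each tested gene, without XIST and Y-linked genes; red and blue points passed an adjusted p of 0.05. Named genes are circled, from RPS10 at 4.09 to LAMP3 at -4.74.

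The 8 largest falls by the rule for named genes were those of LAMP3, AKR1B10, METTL7A, LINC01123, ANTXR1, HSPB6, IL6 and SUCNR1. IL6, an inflammatory cytokine (chromosome 7, 22727147 to 22732002), went from 1724 ± 537 CPM in siCon to 188 ± 17 in siH19 (SD, n = 3 each), a log2 fold change of -3.20 ± 0.22 (SE, adjusted p = 3.4e-06). ANTXR1, a cell surface protein that binds collagen and anthrax toxin (chromosome 2, 69013144 to 69249327), went from 1165 ± 123 to 115 ± 8 CPM, a change of -3.34 ± 0.11 (adjusted p = 2.1e-07). AKR1B10, an aldo-keto reductase, changed by -4.48 ± 0.22 and LAMP3, a lysosomal membrane protein, by -4.74 ± 0.27. The changes were -3.26 ± 0.16 for HSPB6, a small heat shock protein of muscle, -3.59 ± 0.19 for METTL7A, -3.18 ± 0.24 for SUCNR1, the succinate receptor, and -3.38 ± 0.23 for the non-coding LINC01123, which has no single locus in the count table. All of these are log2 values with their SE.

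The largest rises by the rule for named genes were those of RPS10, HIST1H2AI, HSPE1, SULT1E1, ISG15, HIST1H4I, HIST1H3H and RUSC1. ISG15, a ubiquitin-like protein induced by interferon (chromosome 1, 1013467 to 1014539), went from 21.7 ± 3.46 to 188 ± 12 CPM, a log2 fold change of 3.11 ± 0.13 (adjusted p = 6.3e-07). SULT1E1, an estrogen sulfotransferase (chromosome 4, 69841212 to 69860152), rose from 1.37 ± 0.64 to 12.7 ± 2.19 CPM, by 3.18 ± 0.27 on the log2 scale, and RUSC1 rose by 2.97 ± 0.22. RPS10 (4.09 ± 0.21), a ribosomal protein gene, and HSPE1 (3.63 ± 0.16), a mitochondrial chaperonin gene, are uncertain. RPS10 shares 62.5% of its exon bases with RPS10-NUDT3, HSPE1 shares 63.8% with HSPE1-MOB4, and 25 pseudogenes carry the name of HSPE1. The histone values (3.76 for HIST1H2AI, 3.01 for HIST1H4I and 2.98 for HIST1H3H) are uncertain too, because the coding parts of these genes are near-identical copies.

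Genes induced by interferon rose as a group. Of 38 tested members of the interferon list, 30 were higher and 2 lower in siH19, with a median log2 fold change of 0.95. The members with the smallest adjusted p were ISG15, MX1 (1.32 ± 0.09), an antiviral GTPase, and IFIT1 (2.32 ± 0.10) and IFIT3 (1.40 ± 0.09), of a family that acts against viral RNA. IFIT1 went from 56.7 ± 5.68 to 283 ± 9 CPM. The list passed camera with a preset correlation (adjusted p = 2.4e-07), with adjusted p = 0.401 when the correlation was estimated. The inflammatory list moved both ways, with 9 members higher and 17 lower of 31. IL6 and ICAM1 (-1.99 ± 0.10), an adhesion molecule for leukocytes, fell, while TNFAIP6 (2.84 ± 0.18), a hyaluronan-binding protein induced by inflammatory signals, rose. This list did not pass camera (adjusted p = 0.13), but passed with library totals only (0.0314) and without an expression filter (0.0427), in a range from 0.0314 to 0.181 at the preset correlation.

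Most of the listed cell cycle genes rose in siH19. Of 52 tested genes of DNA replication and the G1/S step, 38 rose and 2 fell (median 0.74), among them BLM (2.20 ± 0.16), a DNA helicase, RFC3 (1.75 ± 0.14), a part of the clamp loader, and RRM2 (1.29 ± 0.10), a subunit of ribonucleotide reductase. Of 68 mitotic genes, 43 rose and 2 fell (median 0.65). PRC1, which bundles microtubules in late mitosis, rose by 1.71 ± 0.09, and the spindle checkpoint genes BUB3 and BUB1B rose by 1.32 ± 0.11 and 1.19 ± 0.10. KIF14, a mitotic kinesin, rose by 1.31 ± 0.11. Among the members that did not pass were 5 common markers of dividing cells, picked after their values were seen, with log2 fold changes of 0.12 ± 0.17 for MKI67, 0.09 ± 0.12 for TOP2A, -0.10 ± 0.21 for CDK1, 0.13 ± 0.09 for PCNA and -0.35 ± 0.15 for FOXM1. Of these, MKI67 (0.42), TOP2A (0.38) and PCNA (0.42) passed with library totals only (adjusted p = 0.044, 0.0137 and 0.0013). PCNA also passed with upper quartile scaling (0.22, adjusted p = 0.044), and FOXM1 was lower with RLE scaling (-0.37, adjusted p = 0.0491). Other common markers, also picked after their values were seen, rose, such as MCM2 (1.48), TK1 (1.38), CDC20 (1.10) and CCNB1 (1.04). Of 28 histone genes, 26 rose and 1 fell (median 1.76), with HIST1H3F at 2.23 ± 0.15, HIST1H3G at 2.25 ± 0.17, HIST1H2AB at 2.59 ± 0.21 and HIST1H1C at 2.16 ± 0.18. Camera gave adjusted p = 1.1e-07 for the replication list, 9.2e-07 for the mitotic list and 6.6e-08 for the histone list. With an estimated correlation each had adjusted p = 0.401.

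**Figure D2:**
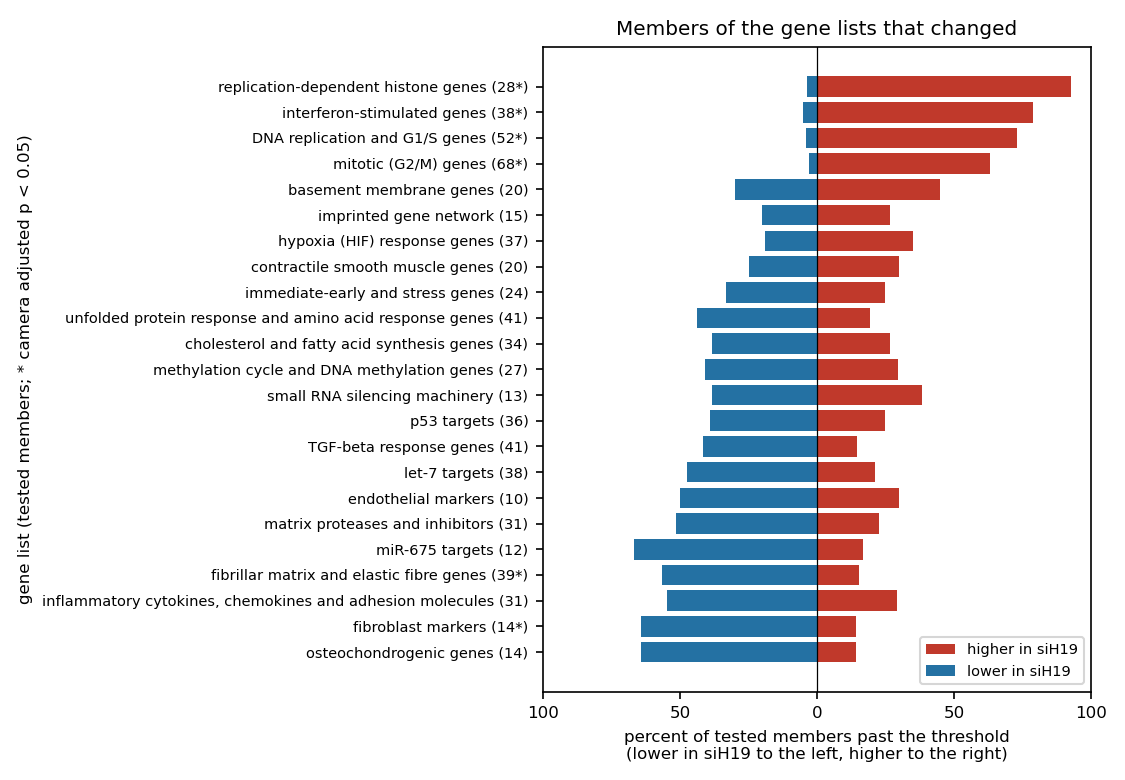
Percent of tested members of each gene list that were higher (red, to the right) or lower (blue, to the left) in siH19 at an edgeR adjusted p under 0.05, with the number of tested members in brackets and a star for a camera adjusted p under 0.05 at the preset correlation. The histone list had 26 of 28 members higher, and the fibrillar matrix list had 22 of 39 members lower.

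Genes of the fibrillar matrix fell more often than they rose. Of 39 tested members of the list of fibrillar collagens, elastic fibre proteins and their enzymes, 22 fell and 6 rose (median -0.49). OGN (-2.53 ± 0.21, log2 ± SE) and LUM (-1.39 ± 0.12), both small leucine-rich proteoglycans, fell, as did LOXL4, a lysyl oxidase relative (-1.80 ± 0.14), and EFEMP1, an elastic fibre protein (-1.26 ± 0.09). The 6 that rose, given here outside the rule for named genes, were ELN (1.30 ± 0.20), FBLN2 (1.21 ± 0.19), COL6A2 (0.59 ± 0.17), FBN1 (0.49 ± 0.08), TNC (0.43 ± 0.10) and MFAP5 (0.35 ± 0.10). ELN is elastin and FBN1 is fibrillin 1, so elastic fibre genes moved both ways. Camera gave adjusted p = 0.0044 for the list, and adjusted p = 0.401 with an estimated correlation. Basement membrane genes moved both ways, with 9 higher and 6 lower of 20. NID2 (-1.31 ± 0.09) and LAMA2 (-1.21 ± 0.12) fell. Of 31 matrix proteases and inhibitors 7 rose and 16 fell, with MMP19 at -1.97 ± 0.12 and CTSL at -1.68 ± 0.12. Neither the basement membrane list (camera adjusted p = 0.612) nor the protease list (0.0578) passed. The protease list did pass with library totals only (0.0147), upper quartile scaling (0.0423), no expression filter (0.0368) or without siCon library 2 (0.0488). Its adjusted p ran from 0.0147 to 0.163 over the alternatives with the preset correlation and was 0.401 with an estimated correlation.

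Smooth muscle genes had no common direction. Of 20 tested contractile genes, 6 were higher and 5 lower in siH19. TAGLN, an actin-binding protein, rose from 191 ± 33 to 298 ± 18 CPM (0.64 ± 0.13, adjusted p = 0.0016). MYL9, the regulatory myosin light chain, fell from 330.4 ± 15.7 to 165 ± 13 CPM, and MYOCD, the coactivator that drives contractile genes, from 8.97 ± 0.54 to 5.05 ± 0.15. CNN1, calponin, passed with a small change (0.42 ± 0.15, adjusted p = 0.038) that was lost without siCon library 2 (adjusted p = 0.112), without siH19 library 1, 2 or 3 (adjusted p = 0.102, 0.103 and 0.0857), and with the trend on gene length (0.0904) or GC content (0.19) removed. Over all alternatives its adjusted p ran from 0.0041 to 0.19. ACTA2, smooth muscle actin, had 84.7 ± 10.7 CPM in siCon and 71.9 ± 3.6 in siH19. Its log2 fold change of -0.24 ± 0.11 did not pass (adjusted p = 0.0796) and became 0.05 with library totals only. It passed without siCon library 1 (-0.30, adjusted p = 0.0029) and with the trend on length (-0.34, adjusted p = 0.0089) or GC content (-0.21, adjusted p = 0.0325) removed, in a range from 0.0029 to 0.745. MYH11, the smooth muscle myosin, had 6, 0 and 1 counts in the siCon libraries and 0, 0 and 1 in the siH19 libraries, too few to test. The list did not pass camera (adjusted p = 0.775). Its median (0.07), its mean (0.06) and camera pointed up, whereas fry pointed down (adjusted p = 0.965).

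**Figure D3:**
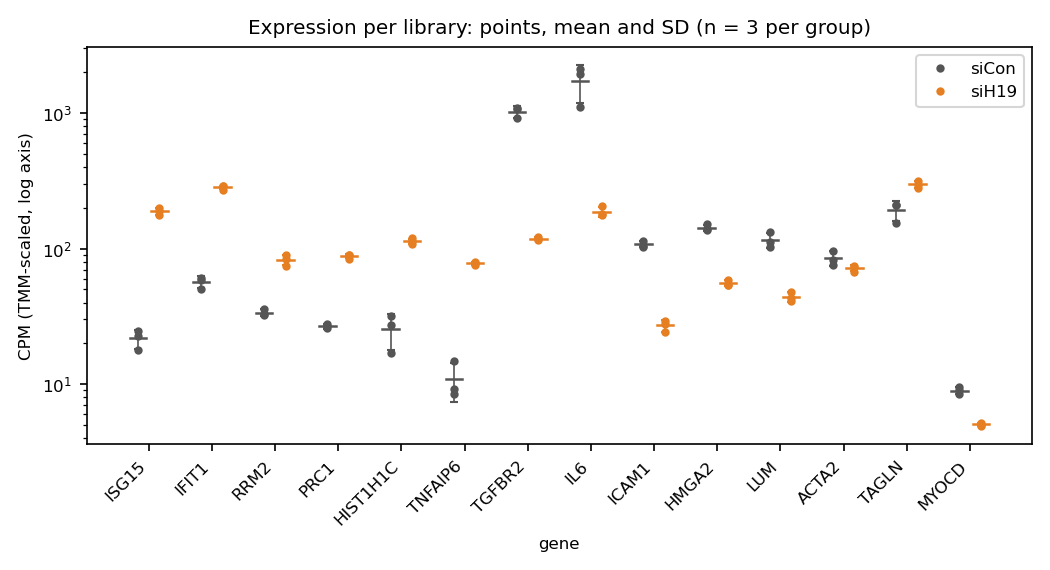
CPM after TMM scaling (log axis) of 14 genes in each library, with grey points for siCon and orange points for siH19, and the mean and SD of each group (n = 3). TGFBR2 lies near 1027 CPM in siCon and 118 in siH19, whereas the points of ACTA2 lie closer together.

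Markers of other cell types were also examined. Of 14 tested fibroblast markers, 9 fell and 2 rose (median -0.73), among them TCF21 (-1.74 ± 0.31), LUM, CCDC80 (-0.93 ± 0.10) and FAP (-0.91 ± 0.11). LUM and 3 more members of this list are also in the fibrillar matrix list. The list passed camera (adjusted p = 0.029), with adjusted p = 0.401 for an estimated correlation. The call was lost without siCon library 1 (adjusted p = 0.056), under a filter of 1 CPM (0.0902), with the GC trend removed (0.0586) and with libraries thinned to 1 depth (0.106). The last of these and the GC setting were added after the data were seen. Over the alternatives with the preset correlation the adjusted p ran from 0.0089 to 0.106. Of 10 endothelial markers 3 rose and 5 fell (camera adjusted p = 0.338), with KDR at -1.70 ± 0.13 and CDH5 at -1.98 ± 0.20. Only 1 of 18 leukocyte and macrophage markers was expressed enough to test, CD68, a lysosomal protein also found outside leukocytes, which went from 1003 ± 259 to 175 ± 9 CPM (-2.52 ± 0.17). Of 3 epithelial markers tested, KRT19 rose by 1.06 ± 0.16. KRT18, which has 65 pseudogenes by name, had 0.42 ± 0.16 (adjusted p = 0.0403), a call lost with the length trend removed (0.097), without siCon library 3 (0.0805) or without siH19 library 1, 2 or 3 (0.129, 0.118 and 0.0531), in a range from 0.0061 to 0.129.

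The lists chosen for H19 itself, and that of the TGF-beta response, did not pass camera, which compares a list with the other genes. They passed fry, which asks only whether a list's genes move one way on balance (adjusted p = 0.0013 for let-7 targets, 0.0013 for miR-675 targets, 0.0146 for the imprinted network and 0.0019 for the TGF-beta response). Of 38 published let-7 targets, relevant because H19 has been described as a sponge for this microRNA, 8 rose and 18 fell (adjusted p = 0.139). IGF2BP2 (-1.58 ± 0.09) and HMGA2 (-1.37 ± 0.09), both growth-related genes of early development, fell. Of 12 targets described for miR-675, 2 rose and 8 fell (adjusted p = 0.0798), with RUNX1 at -1.11 ± 0.13 and SMAD1 at -0.75 ± 0.10. Of 15 genes of the imprinted network 4 rose and 3 fell (adjusted p = 0.607), with NDN at 1.62 ± 0.13 and GNAS at -0.59 ± 0.08. Of 41 genes of the TGF-beta response 6 rose and 17 fell (adjusted p = 0.115). TGFBR2, the type 2 TGF-beta receptor (chromosome 3, 30606502 to 30694141), went from 1027 ± 100 to 118 ± 3 CPM, a log2 fold change of -3.12 ± 0.10 (adjusted p = 2.1e-07). SMAD7, an inhibitor in the same pathway, also fell (-1.07 ± 0.09). Without an expression filter the miR-675 and TGF-beta lists passed camera (adjusted p = 0.0349 and 0.0368), in ranges from 0.0349 to 0.165 and from 0.0368 to 0.181 at the preset correlation. The median of the let-7 list changed sign with library totals only, from -0.23 to 0.06, and so did that of the TGF-beta list, from -0.20 to 0.09.

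The 8805 genes of the authors' deposited table, which reach an adjusted p of 0.0999, comprise 4405 higher and 4400 lower genes. Of these, 8428 could be matched to genes tested here, and all 8428 had the same sign. Of the genes in the authors' deposited table, 7963 passed the edgeR test in the same direction, and Pearson's r between both sets of fold changes was 0.991 across genes, which are not independent replicates. Another 44 genes passed the edgeR test and were not matched to the authors' deposited table. The match used the 8791 genes of that table whose symbol had not been turned into a date. Some of the 44 may thus be in the table under a date. H19 is not among the genes of the authors' deposited table. The table was made from the same libraries and its direction was found from the same counts, so the shared signs do not check the direction between the groups and are not independent evidence.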

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

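The settings with the GC trend removed, with thinning and without MTRNR2L and small RNA genes were chosen after the data were seen; the others were planned. The count of genes higher in siH19 stayed within 1.5 times of 4031 in 20 of 21 settings and that of lower genes within 1.5 times of 3976 in 19 of 21. No named gene or list that had passed changed direction. With library totals only, 2521 genes were lower, because that scaling moves the median of all genes by 0.29. Against a fold of 1.5, 1618 genes were higher and 1708 lower, by construction of that test. The number of lists past camera was 10 without an expression filter and 0 with an estimated correlation (1 at an unadjusted p under 0.05, and 17 with fry). The cause of the first was not tested. Without siCon library 1, which stood apart, 4601 genes were higher and 4407 lower. Leaving out 1 library at a time gave 3228 to 4601 higher genes, 3345 to 4407 lower genes, 5 to 8 lists and 6553 to 8143 genes shared with the authors' deposited table. H19 had too few counts for any setting to give it a fold, so it has no alternative value. The lists of matrix proteases and of osteochondrogenic genes passed camera without siCon library 2 (adjusted p = 0.0488 and 0.0472), with library totals only (0.0147 and 0.0144) and with upper quartile scaling (0.0423 and 0.0465), and the former also without a filter (0.0368). With library totals only, 8 list medians changed sign, none of them of a list that passed. DESeq2 gave no list test.

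Whether the replicate numbers pair the samples is not clear. The deviations of samples with the same number correlated at 0.239, 0.0884 and 0.0455. Both siCon library 1 and siCon library 2 correlated best with the siH19 library of the same number, whereas siCon library 3 correlated best with siH19 library 2. A fit with the replicate block called 4100 genes higher and 3969 lower and left 6 lists. DESeq2 gave 3917 higher and 4027 lower genes, and leaving out MTRNR2L and small RNA genes gave 3994 and 3951.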

Other observations

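The tests on thinned libraries, on GC content, on batches, on site number, reverse complements and presence in H19, and the values of ribosomal protein genes, were chosen after the data were seen. Of 37 hypoxia response genes 13 rose and 7 fell (camera adjusted p = 0.184), and the risen ones include the glycolytic enzymes ENO2 (2.14 ± 0.14, log2 ± SE) and TPI1 (1.66 ± 0.14). Of 41 genes of the unfolded protein and amino acid responses 8 rose and 18 fell (adjusted p = 0.298). HSPA5, the main chaperone of the endoplasmic reticulum, went from 1789 ± 77 to 663 ± 77 CPM (SD, n = 3 each), while SDF2L1, another protein of that compartment, rose by 2.13 ± 0.17. Of 34 genes of cholesterol and fatty acid synthesis 9 rose and 13 fell (adjusted p = 0.538), with STARD4, a sterol carrier, at 2.55 ± 0.11 and FADS1, a fatty acid desaturase, at -0.95 ± 0.08. Of 36 p53 targets 9 rose and 14 fell (adjusted p = 0.607), with CCNG1 at -1.81 ± 0.10 and PLK2 at -0.83 ± 0.10. With library totals only, the medians of the unfolded protein, cholesterol and p53 lists changed sign, to 0.23, 0.18 and 0.10, and that of the unfolded protein list was also above 0 with upper quartile scaling (0.03).

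Of 14 osteochondrogenic genes 2 rose and 9 fell (camera adjusted p = 0.077). This list passed with library totals only (0.0144), upper quartile scaling (0.0465) or without siCon library 2 (0.0472), in a range from 0.0144 to 0.142 at the preset correlation, and had adjusted p = 0.401 with an estimated correlation. TNFRSF11B, the decoy receptor osteoprotegerin, went from 257 ± 15 to 67.2 ± 2.58 CPM, and TRPS1 fell (-1.05 ± 0.09, log2 ± SE). Among 13 genes of small RNA silencing 5 rose and 5 fell (adjusted p = 0.612), with TNRC6B at -1.20 ± 0.10 and DROSHA at -0.98 ± 0.10. Of 27 genes of the methylation cycle and DNA methylation 8 rose and 11 fell (adjusted p = 0.775), with MAT2B at 1.38 ± 0.10 and TDG at 0.95 ± 0.09. Of 24 immediate-early and stress genes 6 rose and 8 fell (adjusted p = 0.916). HSPA1A (-1.56 ± 0.10) and HSPA1B (1.05 ± 0.10) moved in opposite directions, but they are near-identical copies that share reads, so both values are uncertain. With library totals only, the medians of the silencing, methylation and stress lists changed sign, to 0.10, 0.16 and 0.23, and that of the stress list was also above 0 with upper quartile scaling (0.03). Of 73 ribosomal protein genes tested, 47 rose and 14 fell, between -3.08 and 4.09, and the SD of log2 CPM over these genes was 2.04, 1.92 and 1.95 in siCon libraries 1, 2 and 3 and 1.37, 1.36 and 1.35 in the siH19 libraries.

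Of the tested genes, 59.9% differed between the groups. Thinned to the smallest total, the libraries gave 7659 genes past the threshold against 8007 at full depth, which argues against depth as the cause of most calls. With the GC trend removed they gave 8778, which argues against GC content in the same way. Of the 10 splits of the libraries into 3 and 3, 1 (the real one) gave as many genes. The highest of the others gave 0 with edgeR (99 at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05. Each of the others mixes siCon and siH19 libraries on both sides. Any difference between the groups, also one from a batch, then adds to the spread and lowers the calls, so the 0 does not tell its cause. Separate handling of the groups cannot be told apart from an effect of the siRNA, because no batch is given, and the ratio of the lowest siH19 total to the highest siCon total (1.5223), already known when it was taken up, does not decide it.

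Of 16153 7-mers searched in the 3' UTRs of 11422 genes, GCAGTAC stood apart. Genes with it were higher in siH19, that is lower in siCon, than genes without it, by 0.35 ± 0.03 (log2, z = 10.2). The group means after regression were -0.02 without a site, 0.32 for 1 site and 0.54 for 2 or more. Its z led that of GCAATAC, the next 7-mer without 6 adjacent bases in common with it but with most positions the same, by 4.3979. Its reverse complement had z = 0.479, so the difference goes with 1 strand. The same held for CCACCCC, ACATCAA and CATCAAA, described below, whose reverse complements had z = -0.149, -0.354 and 0.689. The strand thus does not tell a seed site from base composition. Off-target silencing by the control siRNA would give a 7-mer that stands apart like GCAGTAC, although an endogenous microRNA with that site was not excluded. Against the shares in searched genes without the site, genes with it had an excess of about 84 higher calls and -70 lower calls. These excesses are not adjusted for UTR length, and genes with a let-7 site had an excess of about 70 lower calls. They therefore do not give a number of silenced genes. On the other side CCACCCC (z = -7.25) led ACATCAA (z = -7.13) by 0.1221, and a lead under 1 had been set in advance as evidence against a seed of the H19 siRNA. This bound was met but was judged unsuited after the result was seen, because 10 of the 15 lowest 7-mers are C-rich. The lead thus sets a possible seed against base composition. The overlapping ACATCAA and CATCAAA (z = -7.05) lie below every permutation (-5.44) and occur in H19, as 12.1% of 7-mers do. CCACCCC also occurs in H19, and 8 7-mers lie below every permutation, so neither property sets ACATCAA apart from C-rich 7-mers. The means after regression were -0.17 for 1 ACATCAA site and -0.13 for 2 or more, and -0.13 and -0.19 for CATCAAA. The excesses, again not adjusted for UTR length, were about 161, 151 and 166 lower calls for CCACCCC, ACATCAA and CATCAAA. For higher calls they were about -172, -141 and -172. They too do not give a number of silenced genes. Genes with a let-7 site differed by -0.0336 ± 0.0236 (SE) after regression, with a mean of 0.01 for 2 or more sites, whereas without regard to UTR length they were more often lower (odds ratio 1.31, Fisher's exact p = 3.7e-05) and less often higher (0.782, p = 0.00036), which leaves open whether let-7 activity changed.

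The rise of histone genes was seen before its tests were written, but not the values that decide them. Other protein-coding genes of the same exon length (202 genes) had a median log2 fold change of 0.306 ± 0.0936 (SE) against 1.76 for the histone genes, which argues against a better recovery of short transcripts as the whole cause. The replication list had a median of 0.7433 and passed camera at the preset correlation, though not with an estimated one (adjusted p = 0.401). More siH19 cells in S phase would give this, but it does not settle it. Of the 52 genes of that list 38 rose, 2 fell and 12, PCNA among them, did not pass. The 73 ribosomal protein genes had a median of 0.64, so a rise of about this size was not particular to replication genes. A batch that follows the groups stays open as well.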
